A study of Macaca mulatta with 6 samples.

How the data were processed

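RNA of laser-captured serotonin neurons from 6 monkeys, 1 array per monkey, was extracted with a column microkit and biotin-labelled, per the labels' protocols. Treatment groups were read from the sample titles, 2 animals each for placebo, estrogen, and estrogen with progesterone. The capsules, the 1 month of treatment and the capture from the dorsal raphe nucleus are also as given in the labels' protocols.

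The deposited table holds 1 linear intensity per probe set and array, as the values show. No log transformation had been applied to them. Each array's mean after trimming 2% from each end was about 200, so the deposited intensities were scaled per array to one target. The summarization software, its version and the detection calls are not given in the sources used here. Such scaling raises all values of an array with little labelled transcript, background included, so a given signal does not mean the same level on 2 arrays; the median signal ran from 49.0 to 170.5.

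Probe sets were named through the platform annotation supplied with the data, with symbols updated by gene number where the RefSeq gene table held it. Of the 52766 probe sets that are not controls, 24956 had 1 gene symbol, 361 had several and 27449 had none and are unnamed here; 24616 of those with 1 symbol matched the gene table. Genes were named only from probe sets with 1 symbol. Genomic positions are not given, because the build of the array's annotation is not named in the sources used here.

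Intensities were taken to log2 after adding 16, and the arrays were quantile normalized because their medians differed by more than 0.1 on the log2 scale. Log2 differences are therefore on the log2(value + 16) scale and understate changes of low signals. Quantile normalization moved the median log2 difference of the tested probe sets from -0.14 to 0.17 for estrogen minus placebo, from -0.17 to -0.03 for both hormones minus placebo, and from 0.06 to -0.22 for both hormones minus estrogen. Control probe sets were left out, and probe sets with a mean at or above the 50th percentile were kept, which left 26383. A linear model with a mean per group was fitted over all 6 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, 3 residual degrees of freedom and two-sided tests, and adjusted p values are Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. With 2 animals against 2 an exact permutation test cannot give a p below 0.333, so none was used. Standard errors are the moderated ones, with a median of 0.945 for a pairwise difference.

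For lists and named genes each gene was represented by its tested probe set with the highest mean over the 6 arrays, giving 9781 genes. Other probe sets of a named gene were computed as alternatives. Before the data were examined, 41 gene lists were fixed, covering serotonin and steroid biology, cell survival, metabolism, proteostasis, synapses, channels, signaling and markers of other cell types; 40 had 5 or more tested genes, and the erythrocyte markers did not, with 0 of 4 above the floor on all 3 high-signal arrays. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Camera compares a list with all other genes, and fry tests whether its genes move one way.

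The rule for named genes was also fixed before the data were examined. In each pairwise comparison it takes the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, and fills open places by the smallest unadjusted p among genes with a log2 difference of at least 1 and groups that do not overlap. Since no gene passed, all places were filled in the second way, among 9130 genes after uncharacterized loci were left out. It adds 12 genes of serotonin transmission and steroid receptors, and up to 4 members of each list described, those past the threshold over the list alone or otherwise those with the smallest unadjusted p.

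The floor of an array is the 95th percentile of its 59 control probe sets for bacterial and tag sequences. A gene below it on every array of a group has only a bound, given as at least N-fold from the other group's mean against the higher of the floor and the measured value on each array, on normalized log2 values. Such a bound allows for the floor alone. It holds no allowance for the spread between animals or for array signal, so the true change may be smaller. Low-signal arrays are those whose share of probe sets above the floor was below the mean of the 6 arrays. The floor, this grouping, scaling to the 27 hybridization control probe sets, the signal class as a covariate, a fit of the high-signal arrays only and median-centering for the lists were chosen after seeing the data. Settings varied as fixed beforehand were the offset, no quantile normalization, median-centering, other filters, leaving out each array, the replicate number as a block, a trended prior, array weights and fits of 2 groups alone.

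The steps were tested on simulated data for estrogen against placebo with 26383 probe sets and the measured spread. Of 50 probe sets changed by a log2 difference of each size, limma recovered 0 at 1, 1 at 2, 7 at 3 and 41 at 5, with 2 false calls. With the smaller spread between the 2 estrogen arrays, 6, 44, 50 and 50 were recovered, with 19 false calls. A list shifted by 1.5 was called, and 0 of 40 other lists were. Correlation between the genes of a list was not simulated. The 7 measured lists called for both hormones against estrogen had estimated correlations of 0.23 to 0.51. The simulation therefore cannot show how often camera with the preset correlation calls such lists falsely.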

Results

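RNA was measured in serotonin neurons cut by laser capture from the dorsal raphe nucleus, the main source of serotonin fibers to the forebrain, of rhesus macaques. Steroid capsules had been in place under the skin for 1 month. The 6 arrays came from 6 monkeys, 2 given placebo, 2 given estrogen, and 2 given estrogen together with progesterone. Titles of the placebo samples carry the tag Ovx, read here as ovariectomized, and those of the hormone samples name the treatment only. Each array held 52865 probe sets, of which 52766 measured transcripts and 99 were controls. Replicates were separate animals, and 2 per group limits the precision of every difference below.

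The arrays differed in how far transcripts stood above background. The share of probe sets above an array's own floor, the 95th percentile of 59 control probe sets with no expected target, was 37.3% and 36.3% on the placebo arrays, 62.2% and 58.5% on the estrogen arrays, and 49.6% and 28.7% on the arrays of both hormones. That floor lay at signals of 216, 221, 29.99, 51.6, 74.9 and 283 in the same order. Placebo 1, placebo 2 and estrogen+progesterone 2 are called low-signal arrays below, and the other 3 high-signal arrays, a grouping made after the values were seen. The 3 high-signal arrays correlated with each other across the 26383 tested probe sets at r of 0.842 to 0.913, and the placebo pair at 0.518. The pair given both hormones correlated at 0.000477. The grouping by signal is not one by r. The placebo arrays correlated with the high-signal arrays at 0.427 to 0.517, about as with each other. With estrogen+progesterone 2 they correlated at 0.290 to 0.333. On the first principal component, 56.0% of the variance, estrogen+progesterone 2 lay at -239 and the other 5 arrays between -47.2 and 109. These r values are across probe sets, which are not independent replicates.

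**Figure D1:**
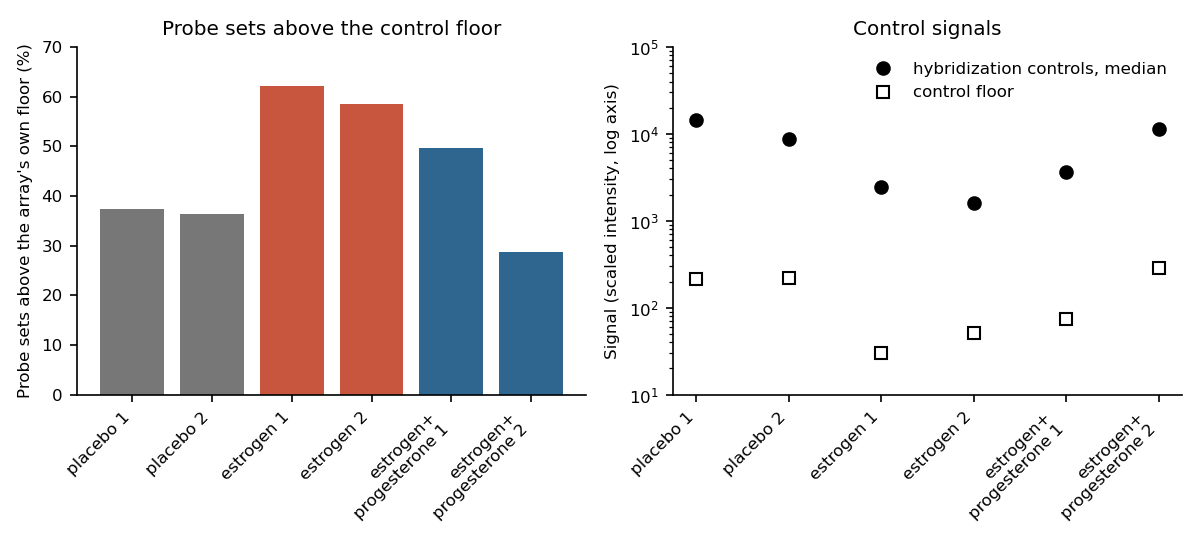
Bars show the percent of probe sets above each array's own control floor, and points on the log axis show the median signal of the hybridization controls (filled circles) and the control floor (open squares) in scaled intensity, 1 array per monkey. Placebo 1, placebo 2 and estrogen+progesterone 2 have the lowest shares, 37.3%, 36.3% and 28.7%, and the highest control signals.

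Transcripts of neurons, astrocytes and myelinating cells were all well above the floor on the high-signal arrays. STMN2, a regulator of microtubules in growing neurites, had signals of 1073 and 2941 with placebo, 6209 and 10949.7 with estrogen, and 5576 and 397 with both hormones. GFAP, the intermediate filament of astrocytes, gave 5358 and 2224 with placebo, 12884 and 18296 with estrogen, and 13706 and 756 with both hormones. MBP, myelin basic protein of oligodendrocytes, gave 30551 and 40944 with placebo, 25757 and 43656 with estrogen, and 39069 and 1849.8 with both hormones. A second MBP probe set gave 661 and 319 with placebo, 5299 and 21082 with estrogen, and 11949 and 456 with both hormones. Of the markers fixed in advance and named on the array, 9 of 10 general neuronal, 11 of 12 astrocyte and 10 of 10 oligodendrocyte genes were above the floor on all 3 high-signal arrays, against 6, 7 and 6 on all 3 low-signal arrays. STMN2, GFAP and MBP, and S100B, TH and SLC6A3 shown with them, were chosen after their values were seen.

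Genes of serotonin transmission and steroid receptors are each given by the probe set with the highest mean. Of the 12 genes to be given whatever their values, 8 were named on the array and 3 of those, SLC18A2, MAOA and FEV, entered the test; SLC6A4, DDC, MAOB and NCOA1 had no named probe set here. TPH2, the tryptophan hydroxylase of serotonin neurons, was above the floor on both estrogen arrays, at 54.0 and 63.2, and on none of the other 4. Its signals there were 126 and 211 with placebo and 12.5 and 243 with both hormones, against higher floors than on the estrogen arrays. Its normalized log2 means were 6.96 with placebo, 6.89 with estrogen and 6.31 with both hormones. MAOA, a monoamine oxidase, was above the floor on all 6 arrays, and FEV, a transcription factor of serotonin neurons, was too. The log2 difference of estrogen minus placebo was 0.41 ± 0.91 (SE, n = 2 monkeys per group) for MAOA, -0.9996 ± 0.84 for FEV and 0.63 ± 1.17 for SLC18A2, the vesicular monoamine transporter, with adjusted p from limma of 0.909, 0.753 and 0.893. The same genes gave 0.19 ± 0.91, -0.54 ± 0.84 and -0.97 ± 1.17 for both hormones minus placebo, and -0.22 ± 0.91, 0.46 ± 0.84 and -1.60 ± 1.17 for both hormones minus estrogen. Without the low-signal array estrogen+progesterone 2, SLC18A2 stood at 0.61 for both hormones minus placebo and -0.02 for both hormones minus estrogen, and MAOA at 0.01 for the latter. Over all 6 arrays, a second SLC18A2 probe set gave 1.23 for both hormones minus placebo and 0.82 for both hormones minus estrogen. Its signals were 45.6 on estrogen+progesterone 1 and 446 on estrogen+progesterone 2. The progesterone receptor gene PGR was below the floor on both estrogen arrays, with signals of 2.61 and 4.84, and above it on 1 placebo array at 313 and on estrogen+progesterone 2 at 351. The estrogen receptor gene ESR1 was below the floor on all 6 arrays, and ESR2 was above it on both estrogen arrays, at 63.4 and 95.3, and on placebo 2 at 247; another of its 3 probe sets was above it on placebo 1 alone, at 318. HTR1A, an autoreceptor, was above it on estrogen 2 alone, at 56.2. PGR, ESR1, ESR2, HTR1A and TPH2 did not enter the test, because their means were below the filter.

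**Figure D2:**
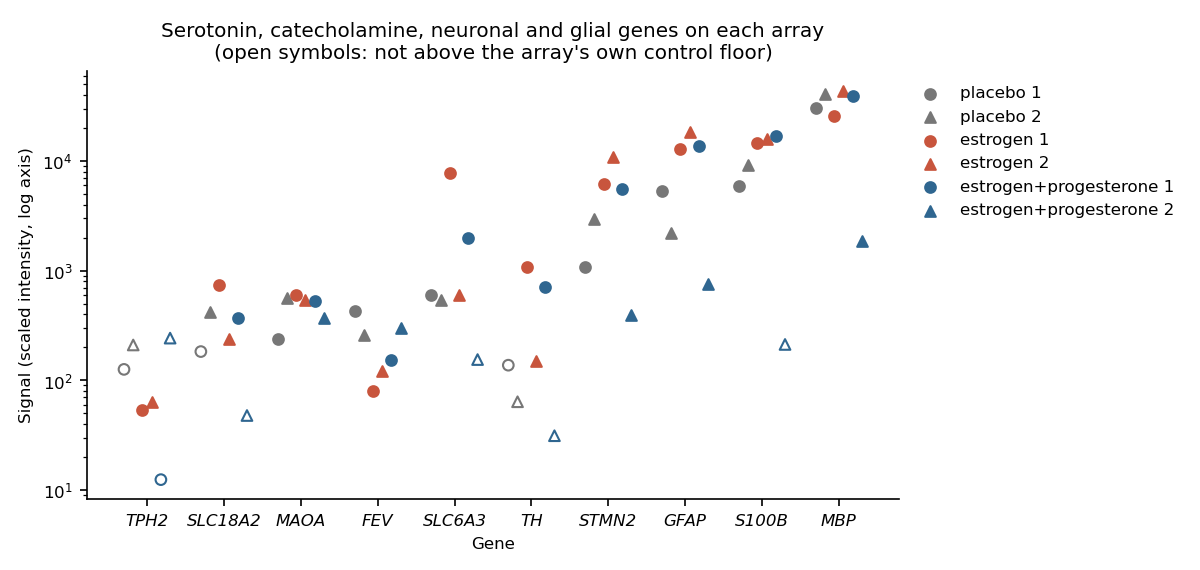
Scaled intensity on a log axis for genes of serotonin transmission (TPH2, SLC18A2, MAOA, FEV), of catecholamine neurons (SLC6A3, TH), of neurons (STMN2), of astrocytes (GFAP, S100B) and of oligodendrocytes (MBP), each point 1 array of 1 monkey, colored by treatment, open where the signal was not above the array's own floor. On the probe set drawn, the one with the highest mean, MBP lies at 25757 or above on 5 arrays and at 1849.8 on estrogen+progesterone 2.

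The comparison of estrogen with placebo asks what estrogen alone did to gene expression in the captured cells. Both placebo arrays were low-signal and both estrogen arrays high-signal, so array signal differs along with treatment. SLC25A3, the mitochondrial phosphate carrier, had signals of 35.8 and 137 with placebo and 2020.4 and 1849 with estrogen, a log2 difference of 4.32 ± 0.92 (SE, n = 2 monkeys per group). ATP5F1B, the catalytic beta subunit of ATP synthase, had 54.8 and 215 with placebo and 1515 and 4759 with estrogen, a log2 difference of 4.21 ± 1.04. PSMB7, a core proteasome subunit, had 14.1 and 109 and then 975 and 1946, a log2 difference of 4.42 ± 0.96. None of these passed the test, with adjusted p = 0.635 from limma for each.

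The other genes named as higher with estrogen were CAPZA2, an actin capping subunit, at 3.57 ± 0.85, the kinetochore gene MIS12 at 4.03 ± 0.97, the growth factor gene GDF6 at 4.19 ± 1.02, EIF2AK3, a kinase of the unfolded protein response, at 3.25 ± 0.83, TMEM181 at 3.30 ± 0.87, DNM2, a dynamin of endocytosis, at 3.07 ± 0.81, and THOC6 at 4.59 ± 1.23. All 10 were below the floor on both placebo arrays and above it on both estrogen arrays. Set against the placebo floor they were higher with estrogen by at least 10.04-fold for ATP5F1B, 7.37-fold for SLC25A3, 5.75-fold for PSMB7, 4.88-fold for MIS12, 4.14-fold for THOC6, 2.96-fold for GDF6, 2.06-fold for TMEM181, 1.94-fold for DNM2, 1.82-fold for CAPZA2 and 1.54-fold for EIF2AK3. These bounds describe the measured arrays and carry no allowance for the spread between animals or for array signal. A second probe set of ATP5F1B gave a log2 difference of 0.45, less than its bound. With the class of low-signal and high-signal arrays as a covariate, a setting added after the values were seen that takes the class difference from the pair given both hormones, the differences were 2.33 for ATP5F1B, 2.79 for SLC25A3, 3.13 for PSMB7, 2.22 for CAPZA2, 4.34 for MIS12, 1.96 for GDF6, 2.25 for EIF2AK3, 1.77 for TMEM181, 2.48 for DNM2 and 0.44 for THOC6. For ATP5F1B, SLC25A3 and THOC6 that was less than the bound. Genes named as lower with estrogen were BMP7, a bone morphogenetic protein, at -3.60 ± 0.87, the chloride transporter gene CLCN5 at -3.05 ± 0.87, GLYAT at -3.07 ± 0.90, TEX29 at -2.96 ± 0.83, BCL6B at -3.05 ± 0.92, MS4A1 at -2.87 ± 0.86, MMP26 at -2.82 ± 0.89, the sulfate transporter gene SLC26A1 at -2.75 ± 0.82, GFRA4, a coreceptor of the RET kinase, at -2.69 ± 0.85, and SULT2A1, a steroid sulfotransferase, at -2.68 ± 0.83. Of these, 6 were below the floor on both estrogen arrays and have only a bound, lower by at least 6.09-fold for CLCN5, 5.17-fold for SULT2A1, 4.66-fold for TEX29, 3.87-fold for BCL6B, 3.34-fold for MS4A1 and 2.97-fold for GLYAT. With the signal class as a covariate the differences were -3.71 for BMP7, -1.59 for CLCN5, -1.47 for GLYAT, -2.63 for TEX29, -1.71 for BCL6B, -1.68 for MS4A1, -2.18 for MMP26, -2.18 for SLC26A1, -3.58 for GFRA4 and -1.99 for SULT2A1. For CLCN5, SULT2A1, BCL6B, MS4A1 and GLYAT that was less than the bound. Their bounds take placebo signals as measured, and some lay close to the placebo floors of 216 and 221, such as GLYAT at 343 and 239. BMP7 had other probe sets with differences of the opposite sign, 1.84 and 0.31, and a second of BCL6B gave -0.65. None of the 20 genes passed, each with adjusted p = 0.635 from limma.

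Of the 40 gene groups fixed in advance, 33 had a median above 0 with estrogen, and none passed a test. With the signal class as a covariate 2 of the 40 had a median above 0, and the values were -2.41 for oxidative phosphorylation, -2.13 for proteasome genes, -0.58 for kinase signaling, -0.69 for astrocyte markers and 0.42 for GABA and glycine genes; the medians of all other groups given here were below 0. Members were above 0 for 30 of 44 genes of oxidative phosphorylation (median log2 difference 0.57), 14 of 21 proteasome genes (0.48), 29 of 37 genes of cAMP, calcium and kinase signaling (0.75) and 13 of 14 genes of GABA and glycine transmission (0.81). In the last group the receptor subunit genes GABRA2 and GABRA4 stood at 3.15 ± 0.92 and 2.46 ± 0.91, and GAD2, an enzyme of GABA synthesis, at 2.09 ± 0.90. In the kinase group CAMK2B stood at 4.02 ± 1.16 and PRKAR1B, a regulatory subunit of protein kinase A, at 2.77 ± 0.86. Of classic estrogen-responsive genes, 9 of 16 were above 0 (median 0.15), with CA12, a carbonic anhydrase, at 3.21 ± 0.86 and the chemokine gene CXCL12 at -1.97 ± 0.85. Pro-apoptotic genes were above 0 for 8 of 15 (median 0.25, HTRA2 3.06 ± 0.97), anti-apoptotic genes for 12 of 17 (0.48, PIM1 2.004 ± 0.84) and DNA repair genes for 16 of 27 (0.18, PMS2 2.32 ± 0.83). For the estrogen-responsive, pro-apoptotic and DNA repair groups the median was above 0 while camera's direction was downward, and for general neuronal markers the median was under 0 while the direction was upward. Steroid receptors and coregulators were above 0 for 9 of 13 (median 0.48), with PAQR7, a membrane progestin receptor, at -1.04 ± 0.82 and EP300 at 1.11 ± 1.05, and genes of serotonin neuron identity for 4 of 10 (-0.14, PTS 1.69 ± 0.87). Of the list members given here, GABRA2, GABRA4, GAD2, PRKAR1B, CA12, HTRA2, PIM1, PMS2 and PTS were below the floor on both placebo arrays and have only a bound. They were higher with estrogen by at least 3.53-fold for GAD2, 2.36-fold for CA12, 2.26-fold for HTRA2, 2.03-fold for PRKAR1B, 2.00-fold for GABRA2, 1.90-fold for PTS, 1.55-fold for GABRA4, 1.19-fold for PMS2 and 1.10-fold for PIM1; CAMK2B was below it on 1 of them. A second tested GAD2 probe set had signals of 49.7 and 318 with placebo and 71.7 and 142 with estrogen. It was above the floor on placebo 2, so the GAD2 bound holds for the probe set used alone. The median of all 9781 genes was 0.28. Astrocyte markers were above 0 for 9 of 11 genes (median 1.16), oligodendrocyte markers for 5 of 10 (-0.05) and general neuronal markers for 4 of 9 (-0.01).

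Across the 26383 probe sets tested, limma called 0 with adjusted p under 0.05 in this comparison, while 2065 had an unadjusted p under 0.05, 1211 of them higher with estrogen, where 1319 are expected by chance; that count ran from 421 to 5117 when 1 array was left out. Of the 40 lists tested with camera, 0 passed, the smallest adjusted p being 0.306 for the kinase list, and 3 had an unadjusted p under 0.05. No list member passed over all genes. Adjusted over the list alone, PSMB7 passed among 21 proteasome genes (adjusted p = 0.0213 from limma) and EIF2AK3 among 16 genes of the unfolded protein response (adjusted p = 0.0476). That adjustment was made in each of the 40 lists by itself, so some passes are expected by chance. Both placebo arrays were low-signal and both estrogen arrays high-signal, so treatment and array signal cannot be told apart in this comparison. With arrays weighted by their spread, limma called 434 probe sets, 288 of them higher with estrogen.

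The comparison of both hormones with placebo asks what the combined treatment did. PEX10, a peroxisome assembly gene, had signals of 453 and 703 with placebo and 15.0 and 48.1 with both hormones, a log2 difference of -4.13 ± 0.83 (SE, n = 2 monkeys per group). The cilium gene CFAP65 stood at -3.45 ± 0.80, DCAKD at -3.26 ± 0.82 and CHRNA3, a nicotinic acetylcholine receptor subunit, at -2.58 ± 0.82. In the other direction, ATF2, a transcription factor of the cAMP response, had signals of 73.6 and 21.5 with placebo and 280.0 and 459 with both hormones, a log2 difference of 3.34 ± 0.85. None passed the test, with adjusted p = 0.992 from limma for each.

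SLC25A3 at 3.45 ± 0.92, PSMB7 at 3.55 ± 0.96, MIS12 at 3.65 ± 0.97, CAPZA2 at 2.93 ± 0.85 and EIF2AK3 at 2.83 ± 0.83 were named as higher here as well as with estrogen alone, over the same placebo arrays. The remaining names were COL14A1, a fibril-associated collagen, at 3.94 ± 0.91, ANKRD13D at 3.42 ± 0.94, RITA1 at 3.33 ± 0.99 and RHBDD2 at 2.92 ± 0.80. All 10 were below the floor on both placebo arrays, and 8 were above it on both arrays of the combined treatment; these were higher by at least 4.03-fold for SLC25A3, 3.73-fold for MIS12, 3.15-fold for PSMB7, 3.14-fold for RITA1, 2.91-fold for ANKRD13D, 2.86-fold for COL14A1, 2.54-fold for ATF2 and 2.21-fold for RHBDD2, and CAPZA2 and EIF2AK3, below it on 1 of those arrays, have no bound. Further genes named as lower were AGAP3 at -3.74 ± 1.21, TRIM3 at -3.04 ± 0.99, SLC26A1 at -2.93 ± 0.82, the zinc transporter gene SLC30A8 at -2.54 ± 0.82, SGCD at -2.54 ± 0.82 and ENPEP, an aminopeptidase, at -2.50 ± 0.81. The 8 other than AGAP3 and TRIM3 were below the floor on both arrays of the combined treatment, lower by at least 4.46-fold for PEX10, 4.11-fold for DCAKD, 3.23-fold for SLC26A1, 3.09-fold for CFAP65, 2.29-fold for CHRNA3, 2.06-fold for ENPEP, 1.95-fold for SLC30A8 and 1.70-fold for SGCD. Without estrogen+progesterone 2 the difference was -1.73 for AGAP3 and -1.79 for TRIM3, and with the signal class it was -5.75 and -4.28. In this comparison the signal class fit gives the same differences as leaving out estrogen+progesterone 1. All 20 kept their sign in both fits, but their selection for groups that do not overlap fixed this in advance. Other probe sets of COL14A1 gave -0.43, -1.43 and 1.27, 1 of TRIM3 gave 1.48, and 1 of DCAKD gave -1.24.

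Most gene groups had medians below 0 with both hormones, again without passing. Members below 0 numbered 30 of 44 for oxidative phosphorylation (median -0.95), 24 of 30 for heat shock proteins and chaperones (-0.59), 23 of 32 for cytosolic ribosomal proteins (-0.56), and 10 of 10 for oligodendrocyte markers (-0.96). In the ribosomal group RPS6 stood at -2.74 ± 1.15 and RPL12 at 2.23 ± 0.82. GABA and glycine genes were above 0 for 10 of 14 (median 0.34), with GABRA2 at 2.45 ± 0.92 and GABRA4 at 2.25 ± 0.91. Both were below the floor on both placebo arrays. GABRA4 was higher by at least 1.34-fold. GABRA2, below it on estrogen+progesterone 2 as well, has no bound. Genes of synapse adhesion and assembly were above 0 for 18 of 33 (0.22), and the median of all genes was -0.10. Without the low-signal array estrogen+progesterone 2 the medians turned, to 0.61 for oxidative phosphorylation, 0.25 for heat shock proteins, 0.62 for ribosomal proteins and 0.30 for oligodendrocyte markers, and were 0.67 for GABA and glycine and 0.53 for synapse adhesion genes. With the signal class as a covariate they were -2.31, -1.64, -1.82, -2.39, 0.51 and 0.03 in the same order.

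Limma called 0 of 26383 probe sets, with 870 at an unadjusted p under 0.05 against 1319 expected by chance, and 305 to 6542 at it when 1 array was left out. Of the 40 lists, camera called 0, the smallest adjusted p being 0.328 for oxidative phosphorylation, and 4 had an unadjusted p under 0.05. No list member passed over all genes or adjusted over the list alone.

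The comparison of both hormones with estrogen asks what progesterone added. By camera with a preset correlation, 7 gene groups were lower with both hormones than with estrogen alone. They cover energy metabolism, proteasome, ribosome and chaperone genes, kinase signaling and neurodegenerative disease genes. Oxidative phosphorylation genes were lower as a group, with 41 of 44 below 0 and a median log2 difference of -1.57 (adjusted p = 0.000794, n = 2 monkeys per group, camera of limma). This call and the other 6 were lost with an estimated correlation (adjusted p = 0.863 for each) and with fry (adjusted p = 0.564), no member passed, and without estrogen+progesterone 2 the median of this group was 0.04 and 0 lists were called. ATP5PO, a stalk subunit of ATP synthase, stood at -3.19 ± 1.51, the complex III genes UQCRC1 and UQCRQ at -2.39 ± 1.22 and -2.18 ± 1.14, and the complex I gene NDUFA6 at -2.30 ± 1.22.

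Proteasome genes were below 0 for 19 of 21 (median -1.33, adjusted p = 0.0217 from camera, and adjusted p = 0.863 with an estimated correlation), with the ATPase gene PSMC5 at -3.11 ± 1.39 and PSMD11 at -2.41 ± 1.17. Cytosolic ribosomal proteins were below 0 for 28 of 32 (-1.22, adjusted p = 0.0217, and 0.863 with an estimated correlation), with RPS3 at -2.92 ± 1.37 and RPS15 at -2.45 ± 1.24. Glycolysis genes were below 0 for 14 of 15 (-1.17, adjusted p = 0.0243, and 0.863 with an estimated correlation), with the aldolase gene ALDOA at -2.60 ± 1.31 and the hexokinase gene HK1 at -2.35 ± 1.24. Heat shock proteins and chaperones were below 0 for 28 of 30 (-1.02, adjusted p = 0.0243, and 0.863 with an estimated correlation), with the chaperonin genes CCT8 and CCT7 at -3.26 ± 1.53 and -2.71 ± 1.29. Genes of cAMP, calcium and kinase signaling were below 0 for 33 of 37 (-0.89, adjusted p = 0.0272, and 0.863 with an estimated correlation), with CAMKK2 at -2.13 ± 1.01 and HRAS at -2.16 ± 1.08. Neurodegenerative disease genes were below 0 for 11 of 12 (-1.52, adjusted p = 0.0283, and 0.863 with an estimated correlation), with APOE, a lipid carrier made mainly by astrocytes, at -3.92 ± 1.57, and SOD1, a superoxide dismutase, at -2.65 ± 1.38. The median of all genes was -0.44. Markers of astrocytes were below 0 for 10 of 11 (median -1.43), of oligodendrocytes for 9 of 10 (-1.52) and of neurons in general for 8 of 9 (-1.54). Without the low-signal array estrogen+progesterone 2, the medians of the 7 groups lay between -0.26 and 0.04, and those of astrocyte, oligodendrocyte and general neuronal markers were -0.04, 0.26 and -0.19.

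**Figure D3:**
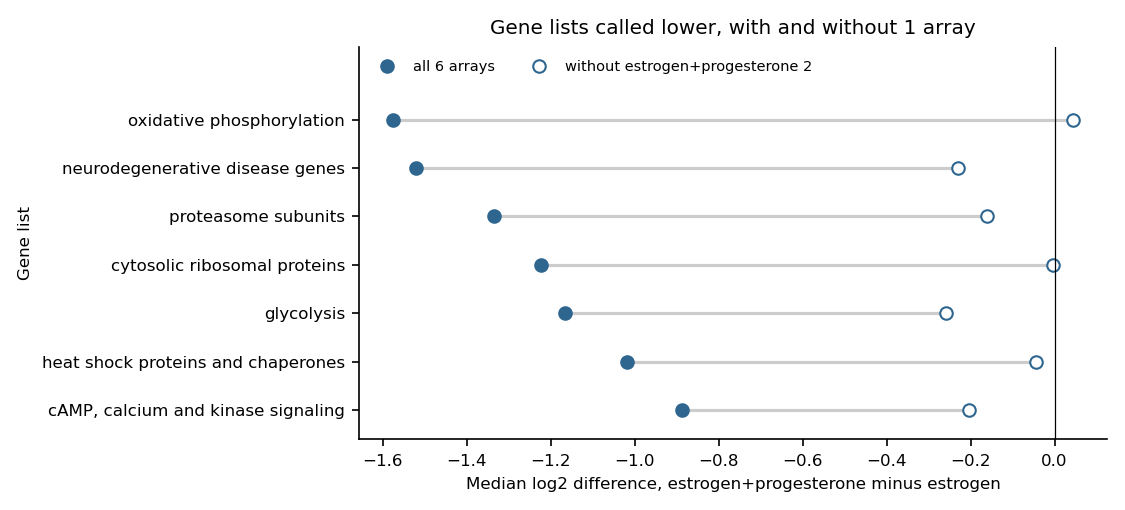
Median log2 difference of both hormones minus estrogen for the 7 gene lists called lower by camera with a preset correlation, over all 6 arrays (filled) and without estrogen+progesterone 2 (open). The medians lie between -1.57 and -0.89 over all arrays, and between -0.26 and 0.04 without that array.

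Among single genes, STRN, a scaffold protein of dendritic spines, had signals of 3.93 and 2.55 with estrogen and 80.4 and 559.5 with both hormones, a log2 difference of 3.77 ± 1.05. TMEM119, a microglial membrane protein gene, stood at 3.05 ± 0.91, SFI1 at 3.65 ± 1.16, GABPB1 at 3.49 ± 1.24, TNFSF14, a tumor necrosis factor family ligand, at 3.13 ± 1.16, PDZK1IP1 at 3.09 ± 1.002, POU5F1 at 2.57 ± 0.93, PGM5 at 2.52 ± 0.91, GLYAT at 2.49 ± 0.90 and the spindle gene TPX2 at 2.32 ± 0.84. The genes named as lower were PTK2B, a calcium-responsive tyrosine kinase, at -2.81 ± 0.89, CADPS2, a priming factor of dense-core vesicles, at -2.88 ± 1.09, the transcription factor gene ETV1 at -2.85 ± 1.07, GTF2E2 at -3.48 ± 1.45, XKRX at -2.98 ± 1.23, DCAKD at -2.19 ± 0.82, CFAP65 at -1.91 ± 0.80, APOE, and the cytoskeletal genes ACTB and TMSB10 at -2.56 ± 1.01 and -3.15 ± 1.33. None passed, each with adjusted p = 0.799 from limma. Genes below the floor on both arrays of a group have only a bound, higher by at least 4.32-fold for TNFSF14, 3.85-fold for STRN, 3.67-fold for TMEM119, 3.09-fold for POU5F1, 2.92-fold for TPX2 and 2.84-fold for PGM5, and lower by at least 2.00-fold for PTK2B, 1.95-fold for DCAKD and 1.06-fold for CFAP65; GLYAT, below it on 3 of these 4 arrays, has none. Without estrogen+progesterone 2 the differences named as higher were 2.36 for STRN, 2.43 for TMEM119, 1.85 for SFI1, 1.63 for GABPB1, 1.72 for TNFSF14, 1.80 for PDZK1IP1, 1.69 for POU5F1, 1.77 for PGM5, 1.69 for GLYAT and 1.74 for TPX2. Those named as lower were -2.20 for PTK2B, -1.47 for CADPS2, -1.65 for ETV1, -0.85 for GTF2E2, -1.15 for XKRX, -2.18 for DCAKD, -1.78 for CFAP65, -0.98 for APOE, -1.19 for ACTB and -0.80 for TMSB10. All 20 kept their sign, but their selection fixed this in advance, since estrogen+progesterone 1 had to lie beyond both estrogen arrays. Other probe sets turned the sign of GABPB1, at -0.15, and of ETV1, at 0.38, and gave 1.27 and 1.14 for SFI1, -1.55 for APOE, -0.86 for TMSB10 and -0.78 for DCAKD.

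Limma called 0 of 26383 probe sets in this comparison, with 464 at an unadjusted p under 0.05 against 1319 expected by chance, and 122 to 10207 at it when 1 array was left out. No list member passed over all genes or adjusted over the list alone. With estrogen+progesterone 1 left out, so that estrogen+progesterone 2 alone stood for the group and was assumed to vary like the others, 4200 probe sets were called.

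Taking the 4 hormone arrays against the 2 placebo arrays asks what any estrogen-containing treatment did. The lists with the highest medians were immediate early genes at 0.73, catecholamine markers at 0.73 and endothelial, mural and meningeal markers at 0.66, and none passed. With the signal class as a covariate these were -0.59, -0.66 and -0.38, and 1 of 40 lists had a median above 0 against 18 without it. Limma called 0 of 26383 probe sets, with 1627 at an unadjusted p under 0.05 (507 to 5505 when 1 array was left out), and camera called 0 of 40 lists, 1 of them with an unadjusted p under 0.05. PSMB7 and EIF2AK3 were the 2 members that passed adjusted over the list alone. They are the same 2 as for estrogen against placebo, whose arrays are all used here again. A test of any difference among the 3 groups called 0 probe sets in limma, with 954 at an unadjusted p under 0.05.

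The log2 differences of the 2 treatments against placebo correlated across 9781 genes at r = 0.494. Simulated arrays with no effect, a shared simulated placebo group and the same spread on every array gave 0.498. The covariance of the measured differences was 0.532 against 0.488 simulated, and 63.6% of genes had the same sign against 66.6%. No calls could be shared, since limma made 0 in either comparison. Without estrogen+progesterone 2 the observed r was 0.905 against 0.407 simulated, with the hormone arrays left all high-signal and the placebo arrays low-signal. Without estrogen+progesterone 1 it was 0.0175 against 0.405. The 2 placebo arrays were not split, since that leaves 1 for each difference, and part of r comes from sharing them. The measured arrays did not spread equally, with a pair r of 0.862 for estrogen, 0.518 for placebo and 0.000477 for both hormones. The simulated values therefore cannot decide whether the 2 treatments share a response.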

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

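Settings using the signal class, the control floor or the hybridization controls, the 3 high-signal arrays alone and median-centered lists were chosen after seeing the data. The count of 0 probe sets held in every comparison under other offsets, filters, normalizations, a trended prior, the signal class as a covariate and fits of 2 groups alone. It changed in 3 cases. At an unadjusted p under 0.01 with at least a 2-fold change, limma gave 335 probe sets for estrogen against placebo, 119 for both hormones against placebo, 23 for both hormones against estrogen and 310 for the hormone groups together. Array weights gave 434 for estrogen against placebo. Leaving out 1 array gave 0 to 4200 for both hormones against estrogen, the 4200 without estrogen+progesterone 1, and 0 elsewhere. The causes were not tested.

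Of 40 lists, both hormones against estrogen kept 7 called with the main settings, and the count became 0 with an estimated correlation, 0 with fry, 12 as deposited, 11 with no filter, 0 with the signal class as a covariate, 0 on the 3 high-signal arrays, and 0 to 9 when 1 array was left out (0 without estrogen+progesterone 2, 3 without estrogen 2, 4 without estrogen+progesterone 1). For estrogen against placebo 0 became 11 as deposited, 2 with median-centered arrays and 4 scaled to hybridization controls, all higher, 4 with the signal class, all lower, and 0 to 2 without 1 array, the 2 without estrogen 1. For both hormones against placebo it became 5 lower with the signal class and 0 to 5 without 1 array, the 5 without estrogen+progesterone 1. For the hormone groups together it became 2 higher as deposited, 5 lower with the signal class and 0 to 2 without 1 array. The covariate fit takes the class difference from the pair of arrays given both hormones. Oxidative phosphorylation without estrogen+progesterone 2 had a median of 0.04 while camera's direction stayed downward; ribosomal proteins turned upward in camera with a median of -0.00314 (range without 1 array -2.67 to -0.00314). In this comparison the fits without estrogen+progesterone 2, with the signal class and on the 3 high-signal arrays give the same differences by construction, so they count as 1 alternative and not as 3 that agree. The correlation of the 2 treatments' differences ran from 0.0175 to 0.905 without 1 array and was 0.963 with the signal class. For the latter, simulated data with no effect and equal spread on all arrays gave 0.706. That value is high because the 2 differences share the placebo arrays and the class difference.

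Across 69 results for single genes and 1085 alternatives, 1061 kept the sign and 24 turned it. Of those that kept it 18 passed the threshold, all for both hormones against estrogen without estrogen+progesterone 1. In 17 the sign of MAOA, SLC18A2 or FEV turned, such as MAOA for estrogen against placebo at -0.55 without placebo 1 and SLC18A2 at -2.53 with the signal class. The other 7 were BMP7 at 1.84 and 0.31, COL14A1 at -0.43 and -1.43, TRIM3 at 1.48, GABPB1 at -0.15 and ETV1 at 0.38, all on other probe sets of the gene. Genes other than MAOA, SLC18A2 and FEV were picked for groups that do not overlap. Leaving out 1 array therefore could not turn their sign. With the replicate number as a block, limma called 0 probe sets in all comparisons and 9 lists for both hormones against estrogen. Deviations of same-numbered arrays correlated at -0.0318, -0.0633 and 0.0822 across probe sets. These values show no sign of pairing by number, but the low signal of estrogen+progesterone 2 could hide one. On signal over background, 22087 probe sets were above the floor on all 3 high-signal arrays, and 5314 of these on all 3 low-signal arrays.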

Other observations

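Transcripts of several cell types other than serotonin neurons were present. Of markers named on the array, 12 of 15 for microglia and blood leukocytes, 13 of 17 for endothelial, mural and meningeal cells and 5 of 8 for GABA and glutamate neurons were above the floor on all 3 high-signal arrays, and the capture was aimed at serotonin neurons. The same held for 3 of 9 catecholamine neuron markers and 5 of 10 cholinergic and peptide neuron markers. Of the genes of serotonin neuron identity and transmission, it held for 9 of 23. TYROBP, an adaptor protein of microglia, had signals of 487 and 379 with placebo, 1015 and 714 with estrogen, and 1015 and 90.0 with both hormones. GAD1, an enzyme of GABA synthesis, had 728 and 1267 with placebo, 2305 and 2003 with estrogen, and 2561 and 16.1 with both hormones. The labels do not give how much tissue around each neuron was cut. TYROBP, GAD1 and the peptide genes that follow were chosen after their values were seen.

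CARTPT, the precursor of the CART peptide, had signals of 306 and 4207 with placebo, 7843 and 311 with estrogen, and 1443 and 292 with both hormones. PENK, the enkephalin precursor, had 391 and 1110.0 with placebo, 3585 and 2045 with estrogen, and 2836 and 7.07 with both hormones, while its second probe set had 131 and 345 with estrogen. NPY had 237 and 496 with placebo, 991 and 233 with estrogen, and 348 and 35.1 with both hormones. No explanation was tested for these.

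All tests in the following 3 paragraphs were chosen only after the result was seen, except the 2 on the 7 gene lists, which were written before those values were computed.

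Splitting the 6 arrays into placebo 1, placebo 2 and estrogen+progesterone 2 against the other 3 gave 843 probe sets past the threshold in limma, 506 lower and 337 higher on the low-signal arrays, and the highest of the 9 other splits into 3 and 3 gave 0; 1 of 10 splits reached the real count, 10 splits are too few for a share under 0.05, and of the splits into 2 and 4 only estrogen+progesterone 2 with placebo 1 (376) or with placebo 2 (91) gave any, so every split with calls puts that array with a placebo array. The hybridization controls, added in a fixed amount, were higher on all 3 of these arrays, the lowest exceeding the highest of the others by 1.23 on the log2 scale, which is consistent with less labelled transcript there. Shorter labelled RNA was also weighed, but the 5' probe sets of GAPDH and ACTB lay below the floor on all 3 arrays, and with these raised to it the log2 3' minus 5' difference of GAPDH was at least 8.42, 8.96 and 8.05 against at most 4.81 on the high-signal arrays, as shorter RNA would give, while that of ACTB was at least 5.82, 4.56 and 1.52 against at most 5.09, an excess of -0.52 at the lower placebo array and -3.56 at estrogen+progesterone 2, which does not settle it. Hormone treatment as labelled would make estrogen+progesterone 2 resemble the other hormone arrays, yet its r was -0.0504 to 0.000477 with these and 0.290 to 0.333 with the placebo arrays, which themselves had 0.427 to 0.517 with the other hormone arrays (its highest with a hormone array minus its lowest with a placebo array, -0.290). Of all probe sets, 28.7% were above the floor on estrogen+progesterone 2. Its low r can therefore come from weak signal, and the test cannot decide on hormone treatment. A wrong label on that array was not tested and stays open, and how many cells were captured per animal is not given in the sources used here.

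The 7 gene lists lower with both hormones than with estrogen may rest on 1 low-signal array: without estrogen+progesterone 2, 0 of the 7 were called, and the median of their medians went from -1.22 to -0.16. An added effect of progesterone would be expected on estrogen+progesterone 1 too, where 0 of the 7 list medians reached the size needed, 50% of that over all arrays. As written beforehand, fewer than 4 of 7 was to count against progesterone. That reading was set aside after the value of 0 was seen, because 1 animal is left, and an effect of progesterone in the other animal cannot be told apart from its low signal.

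TH, the tyrosine hydroxylase of catecholamine synthesis, and SLC6A3, the dopamine transporter, differed between the 2 animals given estrogen. SLC6A3 signals were 7759.9 and 603, and those of TH 1074 and 149, against 1993 and 708 on estrogen+progesterone 1; a second SLC6A3 probe set, at 52.7 and 79.7, did not show it. Each lay at percentile 99.6 of genes of like signal for this difference, but both were picked for it, so an array-wide difference stays open. A candidate explanation is that dopamine neurons, which lie in and near the dorsal raphe, were cut along with serotonin neurons in some animals; the other tested catecholamine markers FOXA1, NR4A2 and DBH differed by 2.49, 0.80 and -0.30, a median of 0.80, at percentile 92.8 of random lists, but FOXA1 on estrogen 2 and DBH on estrogen 1 were not above the floor, which leaves this open. A first form of this test included TH and SLC6A3 themselves and was replaced as circular after its value was seen. Outside the test, other NR4A2 probe sets were also higher on estrogen 1 than estrogen 2. Their signals were 726 and 242, 299 and 145, 288 and 127, and 155 and 61.0. A second TH probe set was below the floor on both arrays, at 7.73 and 4.50.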
